A study of Mus musculus with 5 samples.

How the data were processed

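The data were gene-level read counts from bulk RNA sequencing of CD45+CD64+ cardiac macrophages of mice, 2 samples without and 3 with curcumol, all taken on day 7 after infarction. Each count table column was tied to its sample by the sample's title, and groups and replicate numbers came from the same titles. The labels do not say whether the samples of a group came from separate animals or pools, so p-values measure only the spread between these samples. Per the labels' protocols RNA was extracted with TRIzol. The library kit is given in 2 ways: per the labels' protocols it was a VAHTS Universal kit and per the series' design text a stranded TruSeq kit, so strandedness is not settled and no antisense gene was named.

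The authors deposited counts per gene, as whole numbers without normalization. Per the submitters' processing notes the tools were fastp, HISAT2, HTSeq and Bowtie2, with no versions. The genome build and annotation release are not given in the sources used here, so no coordinates are printed. Reads shared by near-identical genes may be split or lost in such counts. The table held 21289 genes, of which 752 had no count in any library. Names and identifiers (NCBI gene numbers) are those of the deposited table, and 20659 of these numbers were found in the RefSeq table of GRCm38.p6. Transcript lengths and GC content were taken from GENCODE M21 for 17519 genes (82.3%) by gene name, from the longest coding transcript, or the longest of any type where none was coding.

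Totals ranged from 39768705 to 43315822 counts per library, and 3 counts corresponded to 0.0760 and 0.0767 CPM in the untreated libraries. Folds against a group without counts were computed against that floor and cover counting error only. No pair of libraries agreed within sampling noise, with a chi-square per gene of 76.8 to 297, and Pearson's r of log2 CPM was 0.940 between the untreated libraries and 0.983 to 0.985 between the curcumol libraries. Across genes at 3 to 10 CPM the SD of the log2 difference was 1.89 between the untreated libraries and 0.629 to 0.688 between curcumol libraries, and above 100 CPM it was 0.330 and 0.355 to 0.470.

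Curcumol was compared with no treatment in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr (minimum count 10), a quasi-likelihood fit with group as the only term and 3 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment, with 0.05 as the threshold. The square root of the common dispersion was 0.610. SEs were derived from the fold change and the F statistic. An exact permutation test of 2 against 3 samples cannot give a p below 0.1, so none was used for single genes.

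Before the data were examined, 35 gene lists were written: 20 on macrophage biology (interferon-stimulated, STING pathway, interferon gamma with MHC class I, MHC class II, NF-kB targets, reparative, resident, recruited monocyte, lipid-associated, apoptotic cell uptake, complement and Fc receptors, proliferation, glycolysis and hypoxia, respiratory chain, fatty acid oxidation, cholesterol synthesis, NRF2, unfolded protein response, matrix remodelling, lysosome) and 15 on other cells, the gate and RNA quality (T and NK, B, neutrophil, dendritic, mast and related, fibroblast, endothelial, mural, cardiomyocyte, erythroid and platelet, pan-macrophage, dissociation response, mitochondrial, ribosomal protein, histone). Lists with at least 5 tested members were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01), adjusted within each family. Some genes stand in several lists, such as Vegfa, Sqstm1 and Atf3, and NF-kB targets and dissociation genes share 2. The alternatives to camera were an estimated correlation and fry, which tests a list against no change where camera tests it against the other genes.

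Genes named in the text followed a rule fixed before the data were examined: Sting1, Cgas, Tbk1, Irf3, Irf7 and Ifnb1 whatever their values, up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold with libraries that did not overlap and an average log2 CPM of at least 1 (without Gm, LOC, Rik, ribosomal protein, histone and antigen receptor symbols), the 3 members with the smallest p of each list on macrophage biology (6 for interferon-stimulated genes), and the 2 with the smallest p of each other list past the threshold. Members of biology lists past no threshold were left out, except those of the interferon-stimulated list. Not every gene that the rule takes is named in the text.

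Alternatives planned in advance were DESeq2 1.42.0 with its size factors, edgeR with RLE factors or total counts, no filter on low counts, a CPM of at least 1 in 2 samples, limma-voom without and with library weights, the replicate number as a block, leaving out each sample, and a fold cut of 2 with adjusted or unadjusted p. Added after seeing the data were a fit to abundant genes only (average log2 CPM of at least 5) and fits with a lowess trend on transcript length, or on length and GC content, removed from each library. Without an untreated sample the other one is assumed to vary like the curcumol samples.

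The scripts were tested on simulated counts for the 14508 genes of this comparison, with 200 genes changed in each of 3 draws. The changed genes were taken only from those above a minimum expected count, so recovery among genes with low counts was not measured. With one spread for both groups 61.1% of 8-fold, 43.3% of 4-fold and 5.97% of 2-fold changes were recovered and 4.76% of calls were unchanged genes. With each group's own spread these were 60.1%, 38.3% and 6.97%, and 22.5% of calls were unchanged genes. Of 40 unchanged lists of random genes 1 had a camera p under 0.05. These lists were drawn over genes of all levels and simulated with the same spread in both groups. The check therefore cannot show how camera treats groups of unlike spread or lists of abundant genes. Genes were simulated independently, so it also cannot show how camera treats lists whose members move together. The estimated inter-gene correlation was 0.179 in the NF-kB list and 0.374 in the neutrophil list. Random lists for the closing tests (10000 per test) were matched gene by gene to the 200 genes nearest in level. Their genes were drawn independently, so their medians spread less than those of lists whose members move together. Intervals of list medians there are 95% bootstrap intervals over genes (10000 resamples). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.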

Results

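Messenger RNA was sequenced from CD45+CD64+ cells sorted from the infarcted hearts of male C57BL/6JGpt mice on day 7 after myocardial infarction. CD45 marks leukocytes and CD64 is an Fc receptor of monocytes and macrophages, so the gate selects for cardiac monocytes and macrophages. In 3 samples the mice had received curcumol, a sesquiterpene of Curcuma species, at 30 mg/kg by gavage every day, and 2 samples came from mice without it. The series' title names STING, the adaptor of cytosolic DNA sensing, and the type I interferon response of macrophages as its subject, and the comparison asks how curcumol altered the macrophage transcriptome. Total counts were 43315822 and 41663017 in the untreated samples and 41070634, 41117439 and 39768705 in the curcumol samples. The libraries differed more in how many genes they held: 12243 and 12915 genes had a count in the untreated libraries, against 17188, 17078 and 18501 in the curcumol libraries. Among genes at 1 to 3 CPM (counts scaled to a common library total) in the curcumol libraries, 45.4% and 37.6% had no count in the untreated libraries, while above 100 CPM none did. Levels below are mean CPM ± SD over n = 2 untreated and n = 3 curcumol samples, and log2 fold changes are curcumol minus untreated ± SE.

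**Figure D1:**
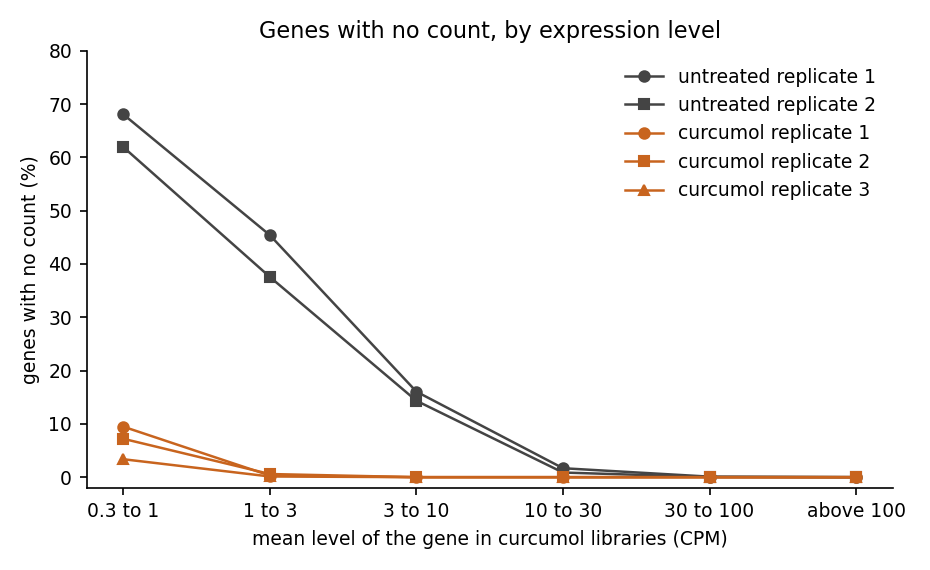
Share of genes with no count (%) in each library against the mean level of the gene in the curcumol libraries (CPM; each curcumol library is set against the other curcumol libraries). The untreated libraries (grey) lack 45.4% and 37.6% of genes at 1 to 3 CPM, and the curcumol libraries (orange) at most 0.591%.

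The genes with the largest falls with curcumol included a cytokine, a chemokine and a costimulatory ligand. Il1a, the cytokine interleukin-1 alpha (NCBI gene 16175), fell from 192 ± 19.7 to 7.58 ± 2.75 CPM (log2 fold change -4.66 ± 0.35, adjusted p = 0.0156). Cxcl1, a neutrophil-attracting chemokine, fell 11.4-fold from 368 ± 142 CPM (-3.51 ± 0.35, adjusted p = 0.0431). Tnfsf9, the ligand of the costimulatory receptor 4-1BB, fell from 483 ± 97.9 to 34.5 ± 15.6 CPM. Cd83, an activation marker of antigen-presenting cells and the gene with the smallest p (NCBI gene 12522), fell from 1191 ± 116 to 174 ± 6.29 CPM (-2.77 ± 0.15, adjusted p = 0.0126). F3, the tissue factor that starts coagulation, fell 25.9-fold, the angiogenic factor Vegfa 8.86-fold and the transcriptional cofactor Ifrd1 9.14-fold. Dusp5, a phosphatase of ERK, fell 5.29-fold, the kinase Plk2 4.93-fold, Rgcc 4.78-fold, the transcription factor Bhlhe40 4.27-fold and the small GTPase Rab20 3.72-fold.

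In all, 30 of 14508 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 10 higher and 20 lower with curcumol. At an unadjusted p under 0.05 there were 2629 higher and 944 lower. The libraries of the 2 groups did not overlap for any of the 30, as for 44.4% of all tested genes, where chance gives 20%. The list of pro-inflammatory NF-kB targets had a median log2 fold change of -1.16 over 49 members. Camera placed it below the other genes (adjusted p = 1.65e-31; adjusted p = 0.182 with an estimated correlation). Of its members 2 fell, Il1a and Cxcl1, and none rose. Adjusted over the list alone 31 fell and 1 rose. Plaur, the urokinase receptor, stood at 524 ± 66.0 and 168 ± 31.9 CPM (adjusted p = 0.0523). A list of immediate early and heat shock genes that tissue dissociation raises moved with it, with a median of -1.05 over 33 members (adjusted p = 1.93e-27; adjusted p = 0.258 with an estimated correlation). Of its members 1 fell, and adjusted over the list alone 22 did. That member was the heat shock gene Hspa1a, 101 ± 7.42 against 31.2 ± 4.41 CPM, whose reads cannot be told with certainty from those of its near-identical copy Hspa1b. Atf3, a stress-induced transcription factor, stood at 1652 ± 165 and 206 ± 104 CPM (adjusted p = 0.0523).

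The number of genes past the threshold rested on single libraries: 1 without curcumol replicate 1, 0 without replicate 2 (2383 at an unadjusted p under 0.05), 19 without replicate 3, and 2950 or 3531 without untreated replicate 1 or 2. DESeq2 called 2656 genes, 1966 higher and 690 lower. All 30 genes kept their sign in each alternative that tested them. Their libraries do not overlap, which largely fixes the sign in advance, so this adds no support.

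**Figure D2:**
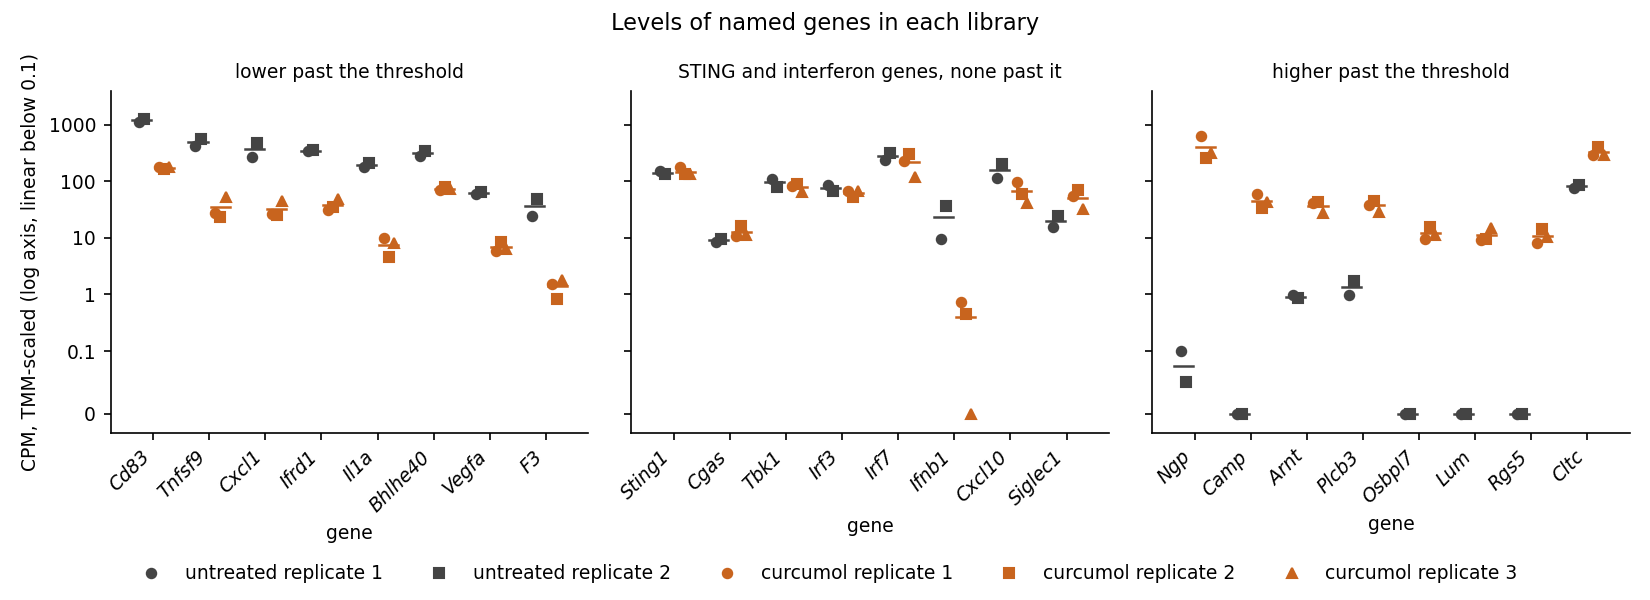
Level of named genes in the 2 untreated (grey) and 3 curcumol (orange) libraries, with a line at each group's mean (TMM-scaled CPM, log axis that is linear below 0.1). Il1a lies at 192 CPM without and 7.58 CPM with curcumol, Sting1 at 142 and 147 CPM, and Camp has no count without curcumol.

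The STING transcript itself was at the same level in both groups. Sting1 (NCBI gene 72512) stood at 142 ± 13.9 CPM without and 147 ± 25.8 CPM with curcumol (log2 fold change 0.05 ± 0.19, 95% interval -0.42 to 0.52, adjusted p = 0.916). Its sign turned without untreated replicate 2 (-0.02) or curcumol replicate 1 (-0.10). The DNA sensor Cgas (0.49 ± 0.40), the kinase Tbk1 (-0.27 ± 0.22) and the transcription factors Irf3 (-0.30 ± 0.20) and Irf7 (-0.37 ± 0.38) did not pass the test, with adjusted p from 0.430 to 0.622. Ifnb1, which encodes interferon beta, stood at 9.61 and 37.2 CPM in the untreated libraries and at 0.741, 0.454 and 0 CPM in the curcumol libraries. This log2 difference of -5.87 ± 1.40 did not pass (adjusted p = 0.0725). Over the alternatives its adjusted p ranged from 7.14e-05 with DESeq2 to 0.261 with a replicate block. Fits without 1 untreated replicate drop the spread between 9.61 and 37.2 CPM, so their p-values are not given. The list of cGAS-STING components had a median of -0.18 over 26 members, 17 of them negative, and no member passed over all genes or adjusted over the list alone. Camera placed it below the other genes (adjusted p = 0.0430; adjusted p = 0.460 with an estimated correlation). Besides Ifnb1 its members with the smallest p were Lrrc8a, a subunit of a volume-regulated anion channel, at 16.8 ± 7.07 and 51.5 ± 25.2 CPM, and the palmitoyltransferase Zdhhc1 at 5.06 ± 1.55 and 13.1 ± 2.63 CPM (adjusted p = 0.0968 and 0.122). The list's call ended without untreated replicate 1 (median -0.11), untreated replicate 2 (-0.11) or curcumol replicate 3 (-0.01), and its median was -0.29 without curcumol replicate 1. The call also ended with total counts (0.00267), DESeq2 (-0.20), a CPM of at least 1 (-0.20), a replicate block (0.00356) and among abundant genes (-0.13).

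Interferon-stimulated genes were not separated by treatment. Of 62 members 31 had a positive and 31 a negative log2 fold change, and none passed the threshold over all genes or adjusted over the list alone. The libraries did not overlap for 6 higher and 8 lower members (22.6%, where chance gives 20% and all tested genes showed 44.4%). The list's median was 0.03 and its mean 0.19, while camera's direction was downward (adjusted p = 0.196; adjusted p = 0.886 with an estimated correlation). The mean log2 CPM of the list was 5.38 and 5.91 in the untreated libraries and 6.08, 6.23 and 5.19 in the curcumol libraries, which span the untreated range. The members with the smallest p went both ways. Cxcl10, a chemokine that draws T cells, stood at 159 ± 64.4 and 66.0 ± 28.2 CPM, Lgals9 at 557 ± 26.7 and 386 ± 61.0 CPM and Nmi at 62.3 ± 1.26 and 43.8 ± 5.07 CPM. Siglec1, a sialic acid receptor of macrophages, stood at 19.8 ± 5.98 and 51.5 ± 18.6 CPM, Dtx3l at 18.1 ± 0.222 and 51.7 ± 33.8 CPM and Samd9l at 13.1 ± 9.65 and 45.1 ± 21.4 CPM. Adjusted p for these 6 genes lay between 0.0878 and 0.153. Camera called the list lower without untreated replicate 1 (median 0.00094, adjusted p = 0.0301), curcumol replicate 1 (-0.08, 0.0237) or curcumol replicate 2 (-0.19, 0.0136). Its direction turned upward without untreated replicate 2 (0.25) or curcumol replicate 3 (0.31), which did not pass. The list of interferon gamma, guanylate-binding protein and MHC class I genes had a median of 0.22 over 42 members (adjusted p = 0.628), and passed upward without curcumol replicate 3 (0.46, adjusted p = 0.00702) or with a replicate block (0.51, adjusted p = 0.0159). That of MHC class II genes had 0.08 over 16, with camera's direction downward (adjusted p = 0.628).

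**Figure D3:**
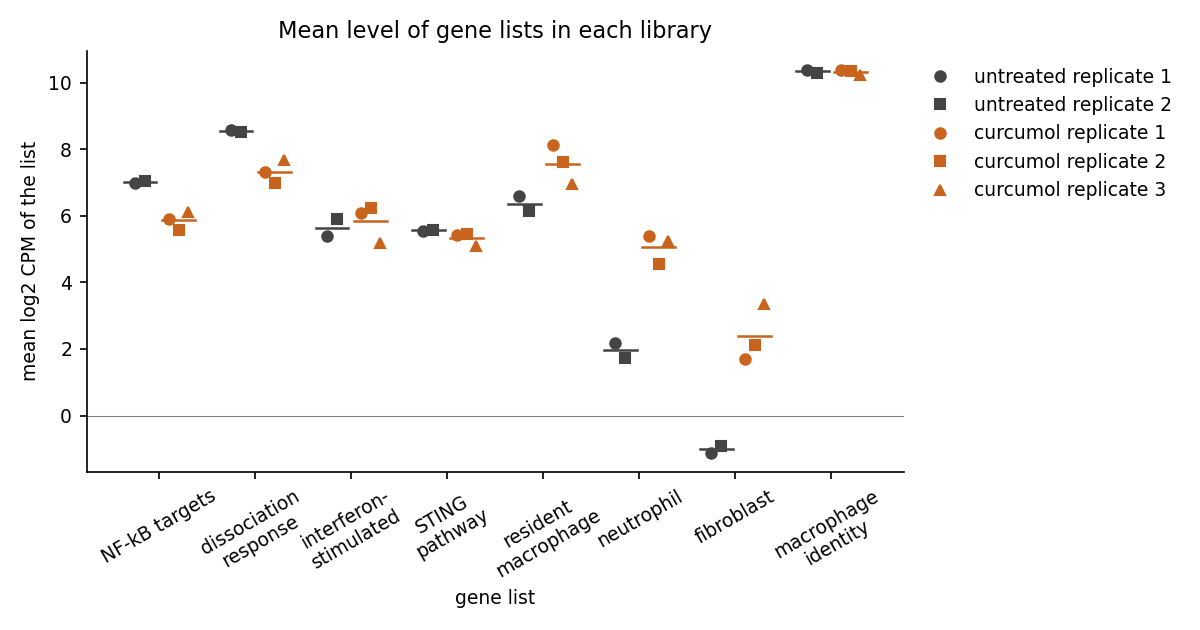
Mean log2 CPM of 8 gene lists in each library, with a line at each group's mean. NF-kB targets lie at 7.00 and 7.05 in the untreated and at 5.92, 5.56 and 6.11 in the curcumol libraries, whereas interferon-stimulated genes lie at 5.38 and 5.91 against 6.08, 6.23 and 5.19.

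Markers of resident cardiac macrophages were higher with curcumol as a list, with a median of 0.98 over 28 members, 25 of them positive (camera adjusted p = 8.47e-05; adjusted p = 0.460 with an estimated correlation). No single member passed over all genes, and adjusted over the list alone 10 rose and 1 fell. C4b, a complement component whose reads may be shared with its near-identical copy C4a, stood at 40.8 ± 5.71 and 363 ± 157 CPM, the mannose receptor Mrc1 at 169 ± 6.07 and 567 ± 164 CPM and the transcription factor Maf at 22.6 ± 2.08 and 57.9 ± 8.39 CPM (adjusted p from 0.0593 to 0.0637). The resident list's call ended without untreated replicate 2 (median 0.87, adjusted p = 0.0919), and its median was 0.58 without curcumol replicate 1. The reparative list had a median of 0.08 and a mean of 0.54 over 32 members, but camera placed it below the other genes (adjusted p = 0.0253; adjusted p = 0.460 with an estimated correlation). Its leading members went both ways: Vegfa fell, the cytokine Il10 stood at 94.3 ± 6.68 and 12.1 ± 5.90 CPM (adjusted p = 0.0523), and Mrc1 was higher as given. That call ended without untreated replicate 1 (median 0.02), curcumol replicate 2 (0.05) or curcumol replicate 3 (0.05), with a CPM of at least 1 (0.06) or a replicate block (0.48), and camera's direction turned upward among abundant genes (0.25). It held with total counts (0.26), limma-voom (0.13; 0.13 with library weights) and the length trend (0.00381) or length and GC trends (-0.02) removed. The median was -0.35 without curcumol replicate 1 and 0.18 without untreated replicate 2. Genes of recruited monocytes (median -0.04 over 32 members, adjusted p = 0.124), uptake of apoptotic cells (0.24 over 30, 0.630), complement and Fc receptors (0.19 over 20, 0.628) and matrix remodelling (-0.03 over 32, mean 1.04, 0.212) did not pass. The recruited list passed downward without curcumol replicate 1 (-0.13, adjusted p = 0.0393) or without a filter on low counts (-0.04, 0.0486).

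Glycolysis and hypoxia-inducible genes were lower with curcumol, with a median of -0.60 over 34 members (adjusted p = 3.88e-14; adjusted p = 0.182 with an estimated correlation). Bhlhe40 and Vegfa fell, no member rose, and adjusted over the list alone 15 fell and 1 rose. The glycolytic enzyme Aldoa stood at 2377 ± 135 and 1280 ± 24.8 CPM (adjusted p = 0.0637). Lipid-associated macrophage genes of the Trem2 type had a median of -0.31 over 34 members (adjusted p = 1.40e-05; adjusted p = 0.460 with an estimated correlation). The lipase Lpl stood at 364 ± 57.0 and 205 ± 9.92 CPM, the tetraspanin Cd9 at 414 ± 50.5 and 229 ± 36.7 CPM and, the other way, the cholesterol exporter Abca1 at 67.7 ± 30.0 and 163 ± 16.3 CPM. NRF2 targets had a median of -0.31 and a mean of 0.01 over 29 members (adjusted p = 7.23e-05; adjusted p = 0.460 with an estimated correlation). The autophagy receptor Sqstm1 stood at 1192 ± 136 and 572 ± 57.7 CPM, heme oxygenase Hmox1 at 1375 ± 308 and 707 ± 93.7 CPM and the superoxide dismutase Sod2 at 222 ± 30.1 and 124 ± 13.2 CPM. The unfolded protein response had a median of -0.21 and a mean of 0.07 over 27 members (adjusted p = 0.000110; adjusted p = 0.460 with an estimated correlation), with Atf3 as above, Atf4 at 171 ± 5.96 CPM without curcumol (log2 difference -1.04 ± 0.17) and Herpud1 at 212 ± 24.8 and 113 ± 15.5 CPM. Lysosome and autophagy genes had a median of -0.16 over 36 members (adjusted p = 0.000236; adjusted p = 0.460 with an estimated correlation), with Sqstm1 as above and the cathepsin Ctsz at 2830 ± 97.3 and 2021 ± 116 CPM. With total counts as the scaling the lipid (-0.12), NRF2 (-0.11) and unfolded protein (-0.02) medians were smaller, and with a replicate block the unfolded protein median was -0.07, with the calls held.

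Smaller shifts were called for nuclear-encoded subunits of the respiratory chain (median -0.10 over 57 members, adjusted p = 0.000704) and proliferation genes (median -0.15, mean 0.01 over 45 members, adjusted p = 0.0166), both with adjusted p = 0.649 with an estimated correlation. Cyc1 stood at 235 ± 15.7 and 162 ± 8.60 CPM, Sdhb at 408 ± 25.1 and 311 ± 30.1 CPM and Ndufs1 at 99.1 ± 34.6 and 65.8 ± 8.71 CPM. The replication clamp Pcna stood at 185 ± 5.15 and 121 ± 4.94 CPM, Birc5 at 58.1 ± 7.23 and 31.4 ± 4.03 CPM and the mitotic kinase Aurka, the other way, at 6.00 ± 1.68 and 14.7 ± 3.32 CPM. No member of these lists or of the lipid, NRF2, unfolded protein and lysosome lists passed over all genes. Adjusted over the list alone 3 NRF2, 6 unfolded protein response and 2 lysosome members fell, 1 unfolded protein response member rose, and none of the lipid, respiratory chain or proliferation members passed. With total counts as the scaling, which moves the median of all genes from 0.15 to 0.34, the medians of the respiratory chain (0.09), lysosome (0.03) and proliferation (0.05) lists were above 0 while camera still placed them below the other genes. The respiratory chain median was -0.00794 with the transcript length trend removed, -0.03 with length and GC trends removed and -0.20 with a replicate block, with the call held (adjusted p = 0.0489, 0.0284 and 1.28e-08). The proliferation call ended without untreated replicate 1 (median -0.03) or curcumol replicate 3 (0.07), with a CPM of at least 1 (-0.17), with a replicate block (0.00480) and among abundant genes (-0.36). Among abundant genes the lipid (-0.22), lysosome (-0.07) and respiratory chain (-0.01) calls ended too. Drawn at the untreated levels of the NF-kB list, random lists had a central median log2 fold change of -0.18. The respiratory chain, lysosome, proliferation, STING and unfolded protein response medians were about that size or smaller. Random lists were not matched to these lists, so a difference from other genes at like levels is not shown. Single libraries also moved medians without ending a call. The proliferation median was -0.23 without untreated replicate 2, -0.08 without curcumol replicate 1 and -0.24 without curcumol replicate 2. Without untreated replicate 1 the NRF2 median was -0.03 and the lysosome median -0.07. Others were lysosome -0.09 and respiratory chain -0.01 without curcumol replicate 2 and respiratory chain -0.21 without curcumol replicate 3. The unfolded protein response median was -0.35 without untreated replicate 1, -0.43 without curcumol replicate 1 and -0.07 without curcumol replicate 3. Fatty acid oxidation (median -0.06, mean 0.42 over 26 members, adjusted p = 0.191) and cholesterol synthesis (0.11 over 24 members with camera's direction downward, adjusted p = 0.722) did not pass. Of the 20 lists on macrophage biology 11 passed with camera's preset correlation, 1 higher and 10 lower, none with an estimated correlation and none with fry (lowest adjusted p = 0.0529).

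**Figure D4:**
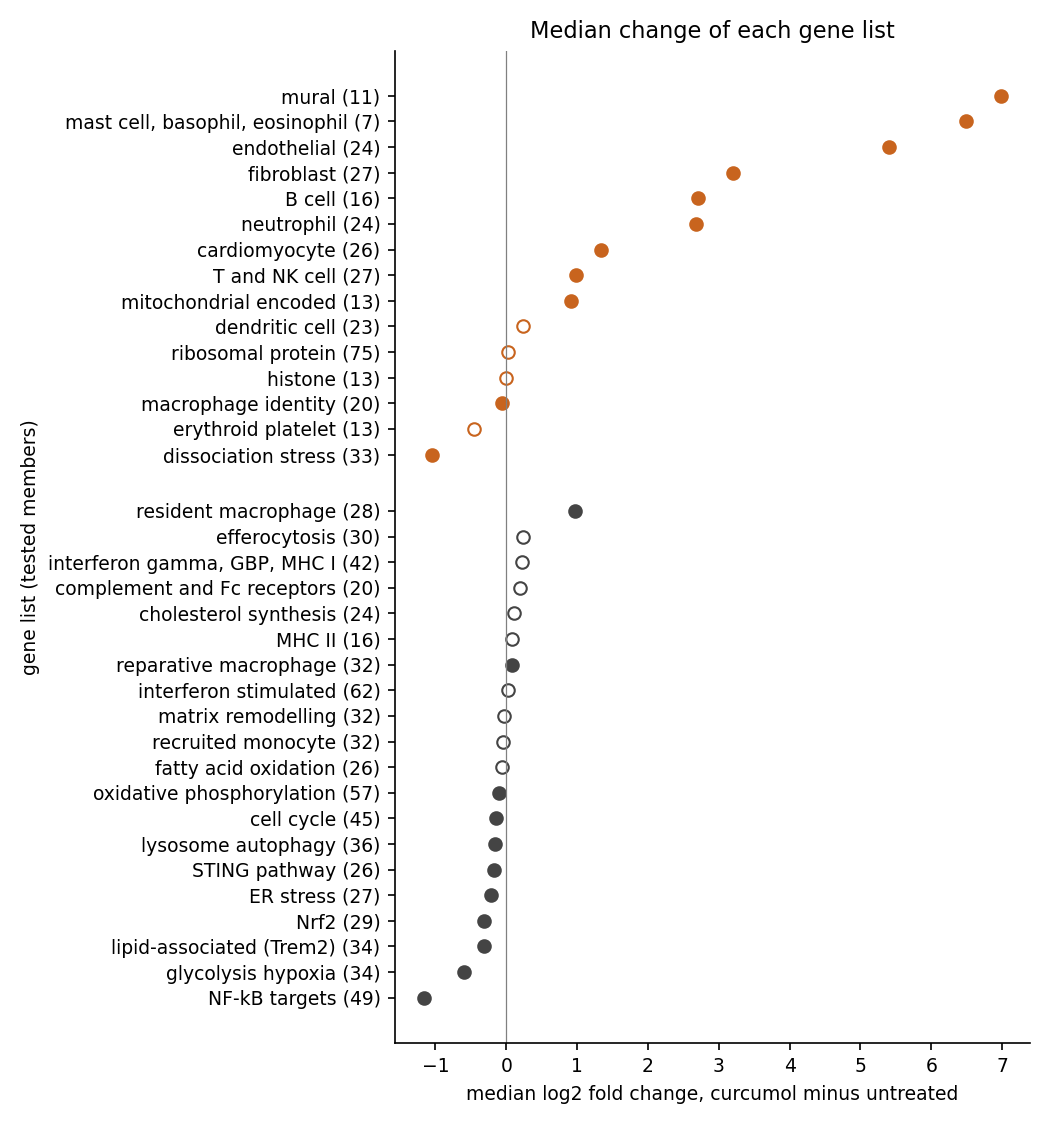
Median log2 fold change (curcumol minus untreated) of each gene list, with the number of tested members in brackets; grey points are lists on macrophage biology and orange points lists of other cell types, the gate and RNA quality. Filled points passed camera with its preset correlation (adjusted p under 0.05), and NF-kB targets are lowest at -1.16 with neutrophil genes at 2.68.

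The genes that rose included markers of cells other than macrophages. Camp, an antimicrobial peptide of neutrophil granules (NCBI gene 12796), had no count in either untreated library and 45.2 ± 13.9 CPM with curcumol, at least 592-fold higher against a floor of 3 counts per library. Ngp, another granule protein, rose from counts of 4 and 2, or 0.0763 ± 0.0355 CPM, to 398 ± 202 CPM (log2 fold change 12.29 ± 0.76, adjusted p = 0.0147). Lum, a fibroblast matrix proteoglycan, was at least 146-fold higher, Rgs5, a pericyte marker, at least 143-fold, Osbpl7 at least 158-fold and S1pr4, a sphingosine 1-phosphate receptor of leukocytes, at least 129-fold, all with no count without curcumol. These folds are bounds for counting error only. At 10 to 30 CPM in the curcumol libraries 1.68% and 0.871% of all genes had no count in the untreated libraries. At 3 to 10 CPM these shares were 16.0% and 14.3%. The matrix proteoglycan Dcn rose 5.19-fold to 67.4 ± 15.5 CPM, the transcription factor Arnt from 0.916 ± 0.0659 to 36.9 ± 8.09 CPM, the phospholipase Plcb3 from 1.35 ± 0.513 to 37.3 ± 8.16 CPM and the clathrin heavy chain Cltc 3.94-fold to 323 ± 66.2 CPM.

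Among the 15 lists on other cells, the gate and RNA quality, 11 passed, 9 higher and 2 lower, none with an estimated correlation and 7 with fry (lowest adjusted p = 0.0188). Neutrophil genes had a median of 2.68 over 24 members (adjusted p = 3.70e-13; adjusted p = 0.296 with an estimated correlation), with Camp and Ngp risen and, adjusted over the list alone, 17 higher and 1 lower. Fibroblast genes had a median of 3.19 over 27 members (adjusted p = 6.34e-07; 0.332 with an estimated correlation), with Lum and Dcn risen and 15 higher and 1 lower adjusted over the list alone. With members that had no count in the untreated libraries set to their lower bound, the fibroblast median was 2.61. Camera was run on the fitted values only. Of all genes at 1 to 3 CPM in the curcumol libraries, 45.4% and 37.6% had no count in the untreated libraries. A marker at 0 and that level is therefore not unusual. Endothelial genes had a fitted median of 5.40 over 24 members (adjusted p = 7.65e-06; 0.258 with an estimated correlation) and a bounded median of 2.79, with Egfl7 at 0 and 6.43 ± 1.95 CPM, and Rgcc of that list fell. Mural cell genes had a fitted median of 6.98 over 11 members (adjusted p = 0.000350; 0.296) and a bounded median of 2.55, with Rgs5 risen and Pdgfrb at 0 and 1.61 ± 0.260 CPM. B cell genes had a fitted median of 2.71 over 16 members (adjusted p = 5.17e-05; 0.296) and a bounded median of 2.25, with Fcmr at 0.0128 ± 0.0181 and 9.81 ± 4.19 CPM and Mzb1 at 0 and 4.78 ± 3.85 CPM. T and NK cell genes had a median of 0.99 over 27 members (adjusted p = 0.0475; 0.477), with Gzmb at 0 and 6.47 ± 2.49 CPM and Prf1 at 0 and 2.63 ± 0.894 CPM. Cardiomyocyte genes had a median of 1.33 over 26 members (adjusted p = 0.00834; 0.332), with Ckmt2 at 0 and 5.22 ± 1.75 CPM and Myl3 at 0.0507 ± 0.0717 and 9.29 ± 0.783 CPM. Mast cell, basophil and eosinophil genes had a fitted median of 6.49 over 7 members (adjusted p = 0.0475; 0.296) and a bounded median of 3.01, with Kit at 0 and 2.22 ± 1.71 CPM and Gata2 at 0 and 1.15 ± 0.296 CPM. Messenger RNAs of the mitochondrial genome had a median of 0.91 over 13 members (adjusted p = 0.000719; 0.441), with ND6 at 79.7 ± 23.4 and 196 ± 32.5 CPM and ND4 at 459 ± 132 and 971 ± 196 CPM. Pan-macrophage markers had a median of -0.06 and a mean of -0.01 over 20 members (camera adjusted p = 0.0420; 0.361 with an estimated correlation). Of these members 8 had a positive and 12 a negative log2 fold change. Cd14, which also stands in the NF-kB list, was at 3727 ± 39.7 and 1539 ± 356 CPM and Cd68 at 3421 ± 353 and 1941 ± 182 CPM. Dendritic cell (median 0.24 over 23 members, adjusted p = 0.474), erythroid and platelet (-0.45 over 13, mean 0.90, 0.221), ribosomal protein (0.03 over 75 with camera's direction downward, 0.106) and histone genes (0.00171 over 13, mean 1.15, 0.913) did not pass. Without curcumol replicate 3 the erythroid list (-0.68, adjusted p = 0.0326) and the ribosomal protein list (-0.15, adjusted p = 1.86e-05) passed downward. The erythroid list also did with a CPM of at least 1 (-0.59, 0.0355), and the ribosomal protein list without a filter (0.03, 0.0311), with library weights (0.02, 0.0321) and with a replicate block (-0.14).

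Several of these calls rested on single libraries. The T and NK cell call ended without curcumol replicate 2 (median 0.46), the mitochondrial call without untreated replicate 1 (0.62) and the mural call without untreated replicate 2 (6.95 as fitted). The mast cell call ended without untreated replicate 1, untreated replicate 2 or curcumol replicate 1 (6.51, 6.52 and 2.60 as fitted), and the pan-macrophage call without untreated replicate 1, untreated replicate 2, curcumol replicate 2 or curcumol replicate 3 (-0.06, 0.01, -0.06 and -0.13). Other settings ended the T and NK cell call (total counts 1.19, DESeq2 0.98), the mast cell call (total counts 6.55, replicate block 5.52) and the pan-macrophage call (total counts 0.13, DESeq2 -0.07, a CPM of at least 1 -0.07, replicate block -0.13, abundant genes 0.03, length trend removed -0.09). Of the calls that held, the fitted fibroblast median was 5.69 and 6.61 without untreated replicates 1 and 2. The fitted B cell median was 7.02, 5.16 and 1.72 without untreated replicate 1, untreated replicate 2 and curcumol replicate 1. Settings that kept the calls moved the mural and mast cell medians with a CPM of at least 1 (2.80 and 2.99), the neutrophil median among abundant genes (1.59), and the T and NK, B cell and cardiomyocyte medians with limma-voom (2.37, 4.45 and 2.06; 2.29, 4.46 and 2.005 with library weights) and a replicate block (2.20, 4.32 and 2.08). The mitochondrial median was 1.43 without untreated replicate 2, the cardiomyocyte median 0.70 without untreated replicate 1 and the pan-macrophage median -0.12 without curcumol replicate 1. These called lists and the higher number of genes in the curcumol libraries moved with treatment alongside the macrophage lists that were called.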

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

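The fits to abundant genes and with length or GC trends removed were chosen after seeing the data, and the cause of a change was not tested unless given. The 30 genes past the threshold (10 higher, 20 lower) became 2656 (1966 and 690) with DESeq2, 10 (4 and 6) with total counts, 416 (313 and 103) without a filter, 98 (57 and 41) with a CPM of at least 1, 1661 (1410 and 251) with limma-voom, 8 (0 and 8) with library weights, 179 (87 and 92) among abundant genes, 18 (6 and 12) with the length trend removed, 16 (6 and 10) with length and GC trends removed, and 2587 (2276 and 311) at an unadjusted p under 0.05 with a 2-fold cut, and stayed at 30 with RLE factors and with a 2-fold cut. The 0 higher genes with library weights stand beside 2858 genes at an unadjusted p under 0.05. Leaving out 1 sample gave 0 to 3531 genes, 0 to 2835 higher and 0 to 696 lower, with none in edgeR without curcumol replicate 2, where 2383 had an unadjusted p under 0.05. The replicate number as a block (1 residual degree of freedom) gave 45 genes, 15 higher and 30 lower, 14 of them among the 30. Deviations of same-numbered samples were barely correlated, with r = 0.0576 for number 1 and -0.0149 for number 2. They span 4278 genes, which are not independent replicates. The deviations of 2 untreated samples mirror each other, so these values cannot decide whether the numbers pair samples. The 11 lists on macrophage biology became 8 with a CPM of at least 1, 10 with DESeq2, 10 with total counts and 12 without a filter. They became 5 among abundant genes, 9 with the replicate block, and 9 to 13 when 1 sample was left out. There were 0 with an estimated correlation (smallest adjusted p 0.182, 2 lists at an unadjusted p under 0.05) and 0 with fry (lowest adjusted p 0.0529). The STING list lost its call with DESeq2 (median -0.199), total counts (0.00267), a CPM of at least 1 (-0.197), the replicate block (0.00356), an estimated correlation (-0.179), fry (-0.179) and abundant genes (-0.134), and its median ranged from -0.288 to -0.00882 when 1 sample was left out. The median of interferon-stimulated genes ranged from -0.186 to 0.312 over left-out samples, and camera's direction turned upward, past no threshold, with the replicate block (0.327) and abundant genes (0.0683). Fry, which tests a list against no change and not against the other genes, gave an upward direction (0.0252), and where it is named below it likewise answers that other question. Uncalled directions turned for histone genes with total counts (0.180), no filter (-0.0327) and the block (0.0546), for cholesterol synthesis with a CPM of at least 1 (0.0989) and fry (0.111), for complement and Fc receptors with limma-voom (0.161), for MHC class II with the block (0.294), length (0.178), length and GC (0.165) and fry (0.0763), for uptake of apoptotic cells with length (0.188) and length and GC (0.180), for ribosomal protein genes among abundant genes (0.127) and with fry (0.0302), for matrix remodelling with fry (-0.0299), and for the called reparative list among abundant genes (0.253). With 1 sample left out, turned directions came within medians of -0.198 to 0.885 for histone genes, -0.230 to 0.257 for MHC class II (turned at 0.161 and 0.257), 0.151 to 0.436 for apoptotic cell uptake, 0.125 to 0.239 for complement (turned at 0.125 and 0.169), -0.146 to 0.127 for ribosomal protein genes, 0.0365 to 0.462 for interferon gamma genes and -0.00593 to 0.2997 for cholesterol synthesis (turned at 0.164). Sting1 ranged from -0.0989 to 0.156, turned at -0.0989 and -0.0244. Otherwise 853 values of named genes kept their side and sign, 188 passed newly and 118 no longer passed, and 481 values of lists kept theirs, 10 passed newly and 69 no longer passed. Low counts limit what genes under 3 CPM can show: at 1 to 3 CPM 45.4% and 37.6% of genes had no count in the untreated libraries, and at 3 to 10 CPM 16.0% and 14.3%.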

Other observations

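The fit to abundant genes, all 3 tests of explanations for the NF-kB targets, both counts for more neutrophil RNA and the bounded lists were chosen after the result was seen. Among 4411 genes with an average log2 CPM of at least 5, 179 passed the threshold, 87 higher and 92 lower with curcumol, and the genes named here were chosen after their values were seen. Among the genes that fell were the cytokine Tnf (log2 fold change -3.38 ± 0.42), the chemokines Ccl4 (-2.71 ± 0.40) and Ccl3 (-2.18 ± 0.39), Il10 (-2.87 ± 0.39), whose product restrains inflammation, and the early response genes Nr4a1 (-2.74 ± 0.41) and Fos (-1.38 ± 0.24). Among the genes that rose were 7 of the resident macrophage list, such as the chemokine Ccl8 (2.57 ± 0.39), the haemoglobin scavenger receptor Cd163 (2.56 ± 0.50), Mrc1 (1.84 ± 0.26), Maf (1.45 ± 0.26) and the transglutaminase F13a1 (1.28 ± 0.28). Txnip (1.96 ± 0.35), an inhibitor of thioredoxin, and the glucocorticoid-induced Tsc22d3 (1.45 ± 0.29) rose as well and stand in none of the lists. Of the NF-kB list 20 members fell, of the dissociation list 10 fell, and of the neutrophil list 8 rose. The abundance filter averaged all libraries, so a gene could pass it through the group where it was high. In this fit Ngp stood at 0.0797 CPM without and 441 CPM with curcumol, Ltf at 1.74 and 187 CPM, and Il1a at 202 and 8.44 CPM. The fit is therefore not free of genes scarce in the untreated libraries, and these counts are not a separate check.

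NF-kB targets were lower with curcumol, with a median log2 fold change of -1.16 over 49 members. The list did not pass in camera with an estimated correlation (adjusted p = 0.182) or in fry (adjusted p = 0.0529). Few distinct molecules in the untreated libraries were first tested on 37 abundant members, with a median of -1.06. Its interval (-1.64 to -0.44) was wholly negative but was not taken as deciding, and a second test was then added. Of 10000 random lists matched on untreated level 0% had a median as low (random medians -0.46 to 0.08, with -0.18 in the middle). That argues against few molecules, with loss set by level alone. Cut-offs for these tests were set after the result was seen. Log2 fold changes were higher for genes with longer transcripts (Spearman's rho 0.223, and 0.301 at an average log2 CPM of at least 5). With tested genes split by length into 4 groups, their median was -0.07 in the shortest and 0.55 in the longest group. This trend thus differed between untreated and curcumol libraries, and its cause was not tested. With the trend with transcript length removed the median of the NF-kB list was -1.10 (-1.47 to -0.54) in place of -1.16. That argues against this trend as the whole cause. Cell handling before lysis stays open and may account for the pattern, since dissociation genes outside the NF-kB list had a median of -1.05 (-1.47 to -0.80). An effect of curcumol on the macrophages stays open as well, untested, and these samples hold no value that separates it from a difference in handling between the groups.

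Transcripts of neutrophils and of stromal cells were higher with curcumol. The CD45+CD64+ gate selects for monocytes and macrophages, and how fully it removed other cells was not measured. In camera with an estimated correlation the neutrophil, fibroblast, endothelial and mural lists did not pass (adjusted p = 0.296, 0.332, 0.258 and 0.296). Fry called the neutrophil, endothelial and mural lists (adjusted p = 0.0318, 0.0188 and 0.0302) but not the fibroblast list (0.0606). Few distinct molecules in the untreated libraries, with loss set by level alone, are argued against as the whole cause. Of 10000 random lists matched on curcumol level 0% had a fitted median as high as the neutrophil (2.68), fibroblast (3.19) or endothelial list (5.40). For the mural list (6.98) the share was 0.9%. These lists rest on 3 of 24, 10 of 27, 12 of 24 and 7 of 11 members with no untreated count. With such genes at their lower bound in all lists the medians were 2.68, 2.61, 2.79 and 2.55, and 0%, 0%, 0% and 1.39% of random lists were as high. Random genes were drawn independently, so a joint loss of the markers of a cell type was not tested and stays open. More neutrophil RNA in the curcumol libraries stays open: of the 10 members most abundant there 8 were higher without overlap, but that choice favours a rise, and of the 10 most abundant in the untreated libraries, a test added later, 6 were (29.5% of all tested genes were), with S100a8 at 171 and 1149 CPM, S100a9 at 87.0 and 533 CPM, Mmp9 at 143 and 184 CPM and Il1r2 at 121 and 84.2 CPM. Whether curcumol changed which cells were sorted stays open, untested.

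Interferon-stimulated genes were lower in curcumol replicate 3 than in curcumol replicates 1 and 2, with a median log2 difference of -0.97 and 60 of 62 members lowest in that library among the 3. A shift of all genes at that level is argued against, since 0% of 10000 random lists matched on level had a median difference as low (random lowest -0.22). That library stood apart in other lists too, with a mean log2 CPM in replicates 1, 2 and 3 of 6.10, 6.32 and 5.33 for interferon gamma genes, 8.12, 7.62 and 6.97 for resident macrophage markers and, upward, 1.69, 2.11 and 3.36 for fibroblast markers. No biological explanation was tested for a difference within a group. The library bears on the comparison, as without it the list had a median of 0.31 in place of 0.03.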
